A study of Caenorhabditis elegans with 2 samples.

How the data were processed

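Chromatin immunoprecipitation with an anti-GFP antibody followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans, and the deposited results were lists of binding sites (peaks). Both samples belong to 1 group and are biological replicates per the labels: young adults at 62.5 hours, grown from larvae synchronised by starvation, in which the gene D2030.7 carried a CRISPR insertion that adds a GFP tag. Chromatin was fragmented by sonication per the labels. A control is named in the labels and was not used here, so no value below has a control level measured in the same way. Each list derives from the alignments and a control per the deposited descriptions of the files.

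There were 8 peak lists: for each replicate and for each of 2 pooled sets, 1 ranked list of candidate peaks and 1 thresholded list. The genome build is ce11 (WBcel235) per the deposited descriptions and the labels. The aligner and the peak caller are not given in the sources used here. The signal value of each peak is the authors' own, taken as deposited from the peak caller; it was used to describe, rank and filter peaks within a list, and never to compare levels between lists. The ranked lists also carry, as deposited by the authors, −log10 of the global irreproducible discovery rate (IDR), a measure of how well 2 inputs rank the same peak. Each thresholded list held the ranked peaks with −log10 IDR of at least 2 (an IDR of 0.01), except for 71 to 103 peaks per list. The authors' thresholded lists derive from 1 further deposited file that the ranked lists do not use and that is not described in the sources used here. A few intervals (3 to 8 per list) were listed 2 times with different summits and were kept as listed.

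The main set was the conservative thresholded list, whose ranked form compares the 2 true replicates. Its ranked form gives both inputs' own signal without saying which replicate each input is. The lists give no read counts, so the depth of each library is unknown and no value here has a counting error; intervals on shares are exact (Clopper-Pearson) 95% binomial intervals over peaks or genes. Peaks, genes and bins of a chromosome are not independent replicates, and neighbouring genes can share a promoter, so p-values across them describe these lists.

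Genes, exons and untranslated regions came from the Ensembl release 115 annotation of WBcel235, with tRNA products from RefSeq matched by WormBase identifier for 607 of 612 tRNA genes. Coordinates are 1-based. A summit was placed in the first class that applied: promoter (1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene), exon, intron or intergenic. For gene lists each promoter summit was given to the gene with the nearest 5′ end, and 28 lists written before the data were examined were compared with all other protein-coding genes (19973 in all) by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment; odds ratios had 0.5 added to each cell. Overlap between replicates (at least 1 bp), genomic class and non-coding genes within 200 bp were set against 1000 random placements on the same chromosomes with widths kept; the smallest p these allow is 0.001 one-sided and 0.002 two-sided. The reciprocal overlap of at least 50% used 100 placements, so its p of 0.0099 is the smallest possible there. Peaks per 500 kb bin (full bins only) were compared by permutation tests with 100000 resamples, smallest p 1e-05, as was the promoter share of the strongest against the weakest of 4 equal groups by signal, smallest p 2e-05. Words of 7 bases, both strands together, were counted once per window in 100 bp at each summit and in 100 bp windows centred 300 bp to each side; words past an adjusted p of 0.05 (two-sided Fisher's exact test) on chromosomes I, III and V were tested again on II, IV and X.

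Named genes followed a rule written before the data were examined: the tagged gene; the 25 protein-coding genes with the highest-signal promoter summits in the main set, where a thresholded peak of each replicate overlapped the same peak; in each list past the threshold the 4 members with the highest signal; and at most 2 in other lists. In the list of small RNA pathway genes some symbols had no match in the annotation and were not used. The procedures were tested on simulated data. When 40% of 1811 placed peaks were planted beside peaks of the other replicate, 41.0% overlapped. Of 2777 random summits with 30 ribosomal protein genes planted among 19973 genes, 31 such genes were found and the list was called, while 20 fully random sets of 2777 summits gave 1 call over 28 lists each. With 100 planted tRNA genes 111 were found, and 1 other class also passed. A planted word was recovered among 10 words that passed in both sets of chromosomes, and 2777 random summits gave 0 words. Random summits lay in promoters in 20.7% of cases against an expected 21.5%. None of 20 uniform sets of 2777 peaks called chromosome X, and removing 1 in 2 of its peaks gave a ratio of 0.503.

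Alternatives fixed before the data were examined were the other pooled list, each replicate's list alone, the stronger 1388 summits of the main list, other windows, other overlap rules, other backgrounds, stratification by upstream length, 1 Mb bins, and 60 bp windows or 6-base words. Leaving out summits at tRNA, snRNA and snoRNA genes, random placements selected in the window of the nearest 5′ end, summits below the threshold as background for non-coding genes, and the share of genes bound on X were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.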

Results

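Binding of the protein encoded by D2030.7 was mapped in whole young adult worms at 62.5 hours by anti-GFP ChIP-seq. D2030.7 (WBGene00008417, chromosome I, 7588580 to 7590565, plus strand, WBcel235) is annotated in RefSeq as a protein with a C2H2-type domain, a zinc finger fold found in many DNA-binding proteins. The gene carries a tag with GFP and short epitopes, so the antibody pulls down the tagged protein with the DNA bound to it. The 2 samples are biological replicates of 1 group, and no second condition was measured. Replicate 1 gave 2464 peaks past the authors' IDR threshold and replicate 2 gave 1811, a ratio of 1.36. The conservative pooled list, used below as the main list, held 2777 peaks, and the other pooled list 3082, a ratio of 1.11. Median peak width in the main list was 336 bp, and the authors' signal ranged from 2.65 to 1268 with a median of 130. Read depth is unknown, since the lists hold no counts.

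The first comparison was between the replicates. Of the replicate 2 peaks, 80.8% (1463 of 1811, 95% interval 78.9 to 82.6%) overlapped a replicate 1 peak, and 62.1% of the replicate 1 peaks (1530 of 2464, interval 60.1 to 64%) overlapped a replicate 2 peak. Random placement gave means of 1.45% and 1.08% (permutation test, one-sided, p = 0.001 for each, the smallest possible). With random ranked peaks of replicate 2 as the chance level, the mean for replicate 1 peaks was 5.35% (permutation p = 0.001). Most peaks without a partner were still candidates in the other replicate: 844 of 934 replicate 1 peaks (90.4%) overlapped a ranked peak of replicate 2. These were weaker, with a median signal in the replicate 1 list of 62.9 against 104.2 for peaks with a partner. Across the 2777 main-list peaks, the 2 inputs' signals had a Spearman rho of 0.73 and a Pearson r of 0.80 on log2 values; over all 67021 ranked peaks rho was 0.29 and r was 0.47. These correlations are across peaks, which are not independent replicates. The main-list peaks were selected by how well the same 2 inputs rank them, so their higher correlation follows in part from that selection.

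Most summits lay in promoter windows of protein-coding genes. In the main list 54.2% of summits (1506 of 2777, interval 52.4 to 56.1%) fell in promoter windows, 2.53-fold above the random mean of 21.5%, and 3.87-fold with a window of 500 bp upstream to 100 bp downstream. Exons held 5.73% of summits against 23.3% at random (0.25-fold, and 0.10-fold for the stronger 1388 summits), introns 18.8% against 31.3% (0.60-fold, and 0.39-fold without summits at small RNA genes), and intergenic sequence 21.2% against 23.9% (permutation tests, two-sided, adjusted p = 0.002 for each class, the smallest possible). In the replicates' own lists the promoter share was 55.5% ± 2.5 (SD, n = 2) and the exon share 4.96% ± 0.409 (SD, n = 2). Of 1340 summits inside the window of their nearest 5′ end and away from tRNA, snRNA and snoRNA genes, 90.2% lay upstream of it, with a median position of -191 bp and quartiles of -349 and -89 bp. Random placements selected in the same window lay upstream in 79.8% of cases with a mean median of -314 bp (permutation test, two-sided, p = 0.002 for each, the smallest possible, chosen after seeing the data). Ranked summits below the threshold were in promoters in 21.8% of cases and in intergenic sequence in 19.1%. Against these, the direction for intergenic summits turned (1.11-fold, Fisher's exact test, p = 0.00681), and with the narrower promoter window intergenic summits did not differ from random placement (0.99-fold, permutation p = 0.749).

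**Figure D1:**
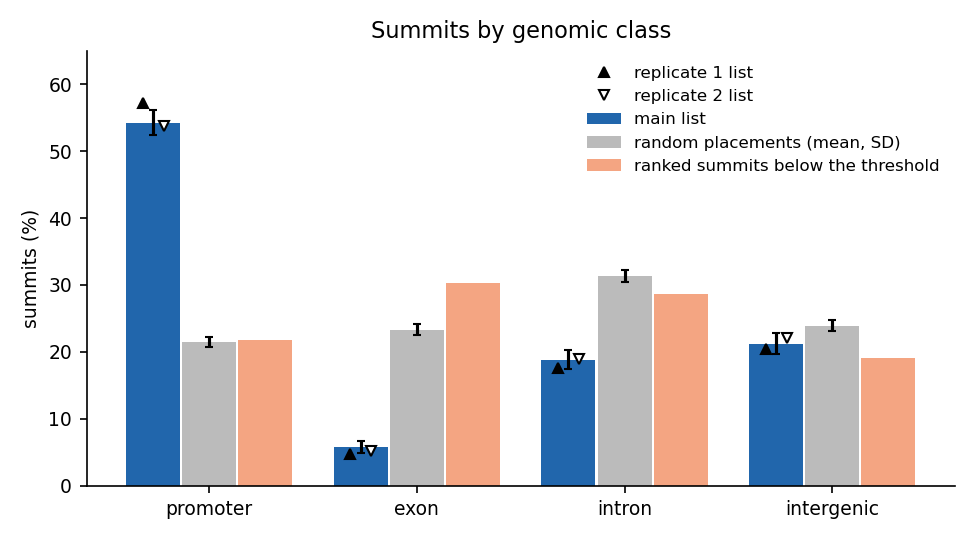
The share of summits (%) in each genomic class is shown for the main list (blue, exact 95% interval), random placements (grey, mean and SD) and ranked summits below the threshold (orange), with each replicate's own list as a triangle. Promoter windows held 54.2% of main-list summits against 21.5% at random.

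Of the 25 protein-coding genes with the strongest promoter peaks, 4 were ribosomal protein genes. A thresholded peak in each replicate was a condition for naming a gene here, so it says nothing about reproducibility. None of the 25 was on chromosome X, which held only 52 of the 1428 genes with a promoter summit. In order of signal they were rps-24, F59C6.18, egrh-2, rpl-3, mog-4, kin-35, cmtr-1, cpg-1, hcp-4, Y17G9B.5, Y75B8A.23, set-16, unc-85, rpl-15, Y53F4B.11, mtcu-2, Y48G10A.2, rib-2, hcp-3, czw-1, his-68, klp-16, K10D2.5, rpl-35 and pygl-1. The rps-24 summit (chromosome IV, 385527) lay in intergenic sequence at -360 bp from the 5′ end, with a signal of 1144 in the pooled list. Its peak had a signal of 688 in the replicate 1 list and 441 in the replicate 2 list. The rpl-3 summit (chromosome III, 3867577, at -277 bp from the 5′ end) had a signal of 1062, mog-4, an RNA helicase gene of the switch from sperm to oocytes (chromosome II, 14561855), 1061 and the eggshell proteoglycan gene cpg-1 (chromosome III, 4489123, at -236 bp) 995. Grouped by known function after the names were seen, and without a test, genes of chromosome segregation were hcp-4, the CENP-C homologue, with a signal of 957 (chromosome I, 3866634, at -696 bp), hcp-3, the centromeric histone, with 756 (chromosome III, 9617122, at -652 bp), and the kinetochore gene czw-1 with 743 (chromosome IV, 7947086, at -261 bp). Chromatin genes were set-16, a histone methyltransferase gene, with 891 (chromosome III, 13643743), unc-85, an Asf1 histone chaperone gene, with 885 (chromosome II, 4701825), and the histone gene his-68 with 715 (chromosome I, 9988966). Histone genes occur in near-identical copies, so reads at his-68 can have come from another copy. The summits given to F59C6.18, cmtr-1 and Y75B8A.23 also lay within 200 bp of a small RNA gene, namely the snoRNA genes F59C6.15 and Y53F4B.47 and the spliced leader RNA gene sls-2.8. Only the mtcu-2 summit of the 25 lay inside another gene, an intron of let-268, and the other 24 were intergenic.

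Germline, cell division and ribosome genes had a promoter peak far more often than other genes. A summit was given to 1428 of 19973 protein-coding genes (7.15%), with 1303 genes from replicate 1's list, 933 from replicate 2's and 789 from both. In the main list 13 of 28 lists were above the rest of the genes. Of the germline and oocyte genes 26 of 43 had a summit (60.5%, interval 44.4 to 75%, odds ratio 20.01, adjusted exact p = 1.51e-18), led by the eggshell genes cpg-1 and cpg-2 and the maternal RNA-binding protein genes mex-1 and pos-1, with signals from 995 to 510. Of the cell cycle and DNA replication genes 30 of 54 had one (55.6%, odds ratio 16.5, adjusted exact p = 1.16e-19), led by hcp-3, the replicative helicase gene mcm-2, hcp-1 and the sliding clamp gene pcn-1. Of the cytosolic ribosomal protein genes 35 of 81 had one (43.2%, interval 32.2 to 54.7%, odds ratio 10.1, adjusted exact p = 1.51e-18), led by rps-24, rpl-3, rpl-15 and rpl-35. In the replicates' own lists these shares were 57.0% ± 14.8 (SD, n = 2) for germline and oocyte genes and 39.5% ± 1.75 (SD, n = 2) for ribosomal protein genes, and cell cycle genes had 53.7% and 46.3%. Among genes with a ranked candidate in the promoter, log2 odds ratios fell from 4.32 to 3.49 for germline and oocyte, from 4.04 to 3.16 for cell cycle and from 3.34 to 2.43 for ribosomal protein genes. When each summit counted for every gene whose window holds it, they were 4.71 for cell cycle and 4.65 for ribosomal protein genes. Among the stronger 1388 summits germline and oocyte genes had 4.97. No control and no list for another tagged protein was used here. Promoters that give peaks in any such experiment therefore cannot be separated from sites of this protein, for these lists or those below.

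Further groups of housekeeping and germline function were bound more often than other genes. Meiosis genes had a summit in 11 of 29 cases (37.9%, odds ratio 8.12, adjusted exact p = 1.16e-05), with syp-4, rec-8, dsb-2 and syp-2 the strongest; syp-4 also lies beside the snRNA gene H27M09.6. With replicate 2's list alone the meiosis call was lost (adjusted exact p = 0.0829). Proteasome subunits had one in 11 of 33 cases (33.3%, odds ratio 6.68, adjusted exact p = 3.32e-05), led by rpn-9, rpn-3, rpn-11 and pas-6, and translation factors in 13 of 41 cases (31.7%, odds ratio 6.20, adjusted p = 1.28e-05), led by eif-2Bgamma, whose summit lay at snRNA genes, and by eef-2, eif-3.C and eef-1G. Oxidative phosphorylation genes had one in 18 of 65 cases (27.7%, odds ratio 5.11, adjusted exact p = 2.35e-06), with cox-5B, atp-1, cox-5A and ndub-8 the strongest. Chromatin and synMuv genes had one in 9 of 33 cases (27.3%, odds ratio 5.06, adjusted exact p = 0.000971), among them lin-9, lin-53, lin-35 and efl-1, components of the DRM complex with the Rb homologue. Splicing factors had one in 8 of 29 cases (27.6%, adjusted exact p = 0.00172), led by snr-4, rsp-6, rsp-1 and rsp-5, and the snr-4 summit lay within 200 bp of the snRNA gene T11F9.15. Aminoacyl-tRNA synthetases (7 of 32, adjusted exact p = 0.0101, with ears-2, aars-2, pars-1 and fars-3), mitochondrial ribosome genes (12 of 70, adjusted p = 0.00704, with mrpl-15, mrpl-28, mrpl-55 and mrpl-23), histones (12 of 72, adjusted p = 0.00786, with his-68, his-42, his-47 and his-61) and small RNA pathway genes (6 of 33, adjusted p = 0.0387, with rde-12, alg-2, ego-1 and pash-1) passed with odds ratios of 2.70 to 3.83. Summits at small RNA genes were among those of his-42 and mrpl-23. The synthetase call was lost with either replicate's list alone, and the mitochondrial ribosome and small RNA pathway calls with replicate 2's list alone. Among the stronger 1388 summits the synthetase, histone, splicing and small RNA pathway calls were lost. The histone and small RNA pathway calls were lost with the narrower promoter window, and the small RNA pathway call also when genes were stratified by upstream length. Among genes with a ranked candidate in the promoter, the synthetase, mitochondrial ribosome, splicing and small RNA pathway calls were lost. There the log2 odds ratios of the calls that stayed fell from 3.02 to 2.27 for meiosis, from 2.74 to 1.80 for proteasome, from 2.63 to 2.03 for translation factor, from 2.35 to 1.54 for oxidative phosphorylation and from 2.34 to 1.59 for chromatin genes. Chromatin genes had 3.00 in replicate 2's list alone. With every gene whose window holds the summit, splicing factors had 3.50 and small RNA pathway genes 2.24.

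Large families with restricted or environmental roles were rarely bound. Chemoreceptor genes had a summit in 8 of 1308 cases (0.612%, odds ratio 0.08, adjusted exact p = 5.23e-31), nuclear hormone receptors in 3 of 269 (1.12%, odds ratio 0.17, adjusted p = 2.35e-05), F-box genes in 7 of 322 (2.17%, odds ratio 0.30, adjusted p = 0.000313) and C-type lectins in 5 of 240 (2.08%, odds ratio 0.30, adjusted p = 0.00191). Cuticle collagens (3 of 174, adjusted exact p = 0.0053), neuropeptides and insulins (2 of 140, adjusted p = 0.00768) and detoxification enzymes (5 of 185, adjusted p = 0.0207) were also below other genes. Several of the few bound members sat beside small RNA genes: both neuropeptide and insulin genes (ins-37 and flp-23), 4 of the 5 detoxification genes, including gst-27, ugt-40 and cyp-43A1, and the collagen gene col-185. The detoxification call was lost with the other pooled list and with each replicate's list alone, the collagen call with replicate 2's list alone, and the neuropeptide call with replicate 1's list alone. Among the stronger 1388 summits the collagen, lectin, detoxification and neuropeptide calls were lost. With the narrower promoter window the log2 odds ratio moved from -3.66 to -4.65 for chemoreceptors, from -2.57 to -3.51 for nuclear hormone receptors, from -1.93 to -2.87 for collagens and from -1.35 to -2.21 for detoxification enzymes. It was -2.98 for chemoreceptors among genes with a ranked candidate, and for nuclear hormone receptors -1.92 in replicate 2's list alone and -1.67 among the stronger summits. Without summits at small RNA genes it was -3.12 for detoxification enzymes and -4.31 for neuropeptides and insulins. The neuropeptide call was also lost when stratified by upstream length, and it and the detoxification call among genes with a ranked candidate. Of the 8 lists that did not pass, the major sperm protein genes had a summit in 0 of 31 cases (interval up to 11.2%) and the intestine genes in 0 of 22 (interval up to 15.4%). Muscle genes had one in 2 of 38 cases (act-2 and unc-45), neuron genes in 1 of 35 (tdc-1), homeobox genes in 4 of 85, bHLH and bZIP genes in 1 of 37 (zip-4), stress genes in 1 of 29 (atfs-1) and chaperones in 7 of 59, led by dnj-28 and hsp-1. Chaperones passed when each summit counted for every gene whose window holds it (log2 odds ratio 2.16, adjusted exact p = 5.7e-06).

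**Figure D2:**
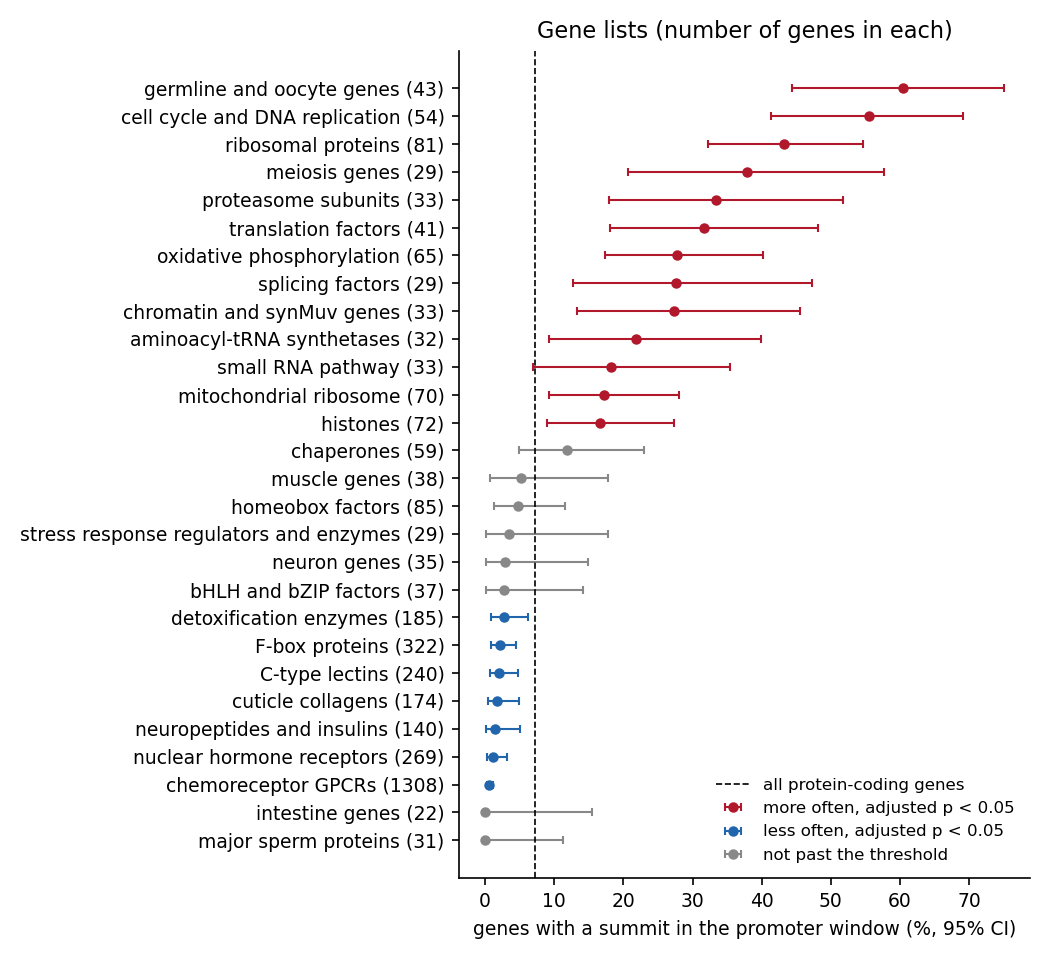
The percentage of genes with a main-list summit in the promoter window is shown for each of the 28 lists with its exact 95% interval; red lists were above and blue lists below other genes, and the dashed line marks all protein-coding genes (7.15%). Germline and oocyte genes reached 60.5% and chemoreceptors 0.612%.

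Genes of small structural RNAs were often bound. Of 612 annotated tRNA genes 451 had a main-list summit within 200 bp (73.7%, interval 70.0 to 77.1%), 65.8-fold above the random mean of 6.85 genes. The snRNA genes, which here include the spliced leader RNA genes, had one in 64 of 129 cases (49.6%, 33.9-fold) and the snoRNA genes in 99 of 346 (28.6%, 18-fold). Each of these classes passed (permutation test, one-sided, p = 0.001, the smallest possible, adjusted p = 0.00225 over 9 classes). Within 500 bp the excess was 31.4-fold for tRNA, 16.1-fold for snRNA, 9.77-fold for snoRNA and 2.91-fold for ncRNA genes. Among the stronger 1388 summits it was 65.4-fold for snRNA and 30.9-fold for snoRNA genes, and in replicate 2's list alone 51.7-fold for snRNA genes. In the replicates' own lists a summit lay at 386 ± 30.4 (SD, n = 2) tRNA genes and 91.5 ± 0.707 (SD, n = 2) snoRNA genes, and at 56 and 64 snRNA genes. A summit counted for every gene within 200 bp, so neighbouring tRNA genes can share a summit, and 421 main-list summits lay at tRNA genes. Tests and medians over tRNA genes treat such neighbours as separate. Of the 451 tRNA genes with a summit, 325 (72.1%) had the strongest one inside the gene, with a median position over all 451 of 22 bp downstream of its 5′ end and quartiles of 4 and 43 bp. The strongest tRNA peak, with a signal of 563, lay at the tRNA-Pro genes C16B8.t2 and C16B8.t3 on chromosome X (3970096 to 3970167 and 3970265 to 3970336), with its summit inside C16B8.t2. The strongest peak of the whole main list, with a signal of 1268, had its summit at position 3932 of chromosome I, beside the snoRNA gene Y74C9A.6 (3747 to 3909). Among spliced leader RNA genes 16 of 30 had a summit, the strongest at sls-2.8 (chromosome III, summit 12250421, signal 897). These genes were singled out after their values were seen, and many spliced leader and tRNA genes exist in near-identical copies. No control and no list for another tagged protein was used here, so sites at tRNA, snRNA and snoRNA genes that appear in any such experiment cannot be separated from sites of this protein.

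The other non-coding classes were bound less. Genes annotated as ncRNA had a summit in 528 of 7764 cases, 4.98-fold above random (adjusted permutation p = 0.00225), and 343 of these 528 lay within 200 bp of a tRNA, snRNA or snoRNA gene. The miRNA genes had one in 10 of 261 cases, 3.05-fold above random (adjusted permutation p = 0.009), and this call was lost against ranked summits below the threshold (adjusted p = 0.0648). The miRNA excess was 5.97-fold in replicate 2's list alone and 5.07-fold among the stronger 1388 summits. The rRNA genes (1 of 20, with 4 further genes at summits past the IDR threshold that the thresholded list leaves out, adjusted permutation p = 0.496), lincRNA genes (12 of 194, adjusted p = 0.231) and antisense RNA genes (3 of 100, adjusted p = 0.825) did not pass. Only 47 of 15363 piRNA genes had a summit, against a random mean of 183 (0.26-fold, and 0.62-fold against ranked summits below the threshold), and the one-sided permutation test for an excess gave p = 1.

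**Figure D3:**
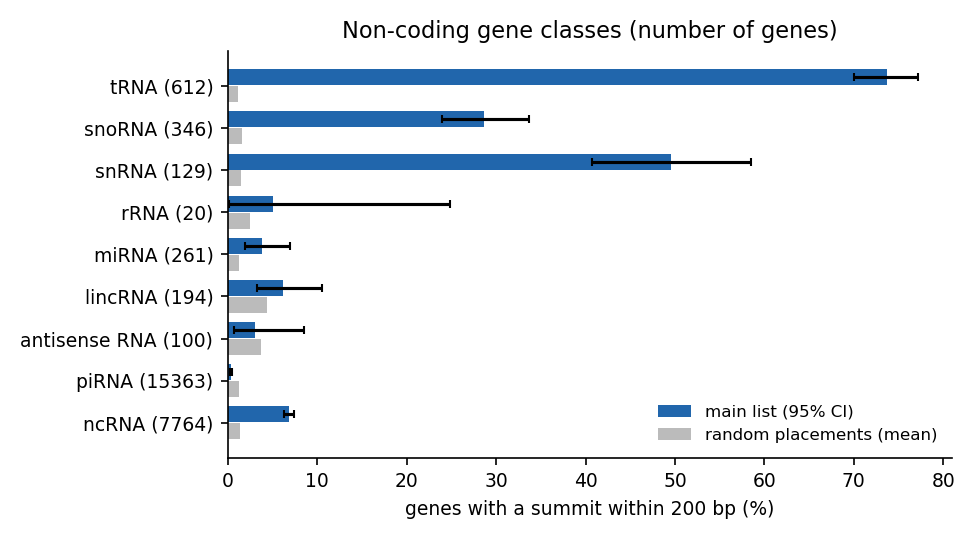
The percentage of genes in each non-coding class with a summit within 200 bp is shown for the main list (blue, exact 95% interval) and for random placements (grey, mean). The bars for tRNA (73.7%), snRNA (49.6%) and snoRNA (28.6%) stand far above their random means.

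Chromosome X carried few peaks apart from those at tRNA genes. It had 7.51 ± 4.98 peaks per 500 kb bin (SD over 35 bins) against 15.1 ± 6.46 on the autosomes (SD over 162 bins), a ratio of 0.50 (permutation test, two-sided, p = 1e-05, the smallest possible, adjusted p = 2e-05 over 2 tests). This ratio takes no account of where the ranked candidates lay, and no test against them was run. Chromosome X held 8.85% of the ranked candidates of replicate 1 and 9.54% of its peaks past the threshold. For replicate 2 these shares were 14.2% and 11.98%. In replicate 1 the share on X was therefore not lower past the threshold than among candidates, while in replicate 2 it was. Of the 265 peaks on X, 193 lay within 200 bp of a tRNA gene and 69 were away from tRNA, snRNA and snoRNA genes. Leaving out summits at these small RNA genes, an alternative chosen after seeing the data, lowered the ratio to 0.16 (permutation p = 1e-05). The density of the remaining summits was 3.89 per Mb on X, 17.9 on V, 22.4 on IV, 24.6 on II, 31.6 on I and 36.1 on III. On X 52 of 2731 protein-coding genes had a promoter summit (1.90%) against 7.98% of autosomal genes (Fisher's exact test, p = 2.52e-39, also chosen after seeing the data). The tests of gene lists took no account of chromosome, so a list with many or few genes on X could pass partly through this difference. At tRNA genes X did not stand below the autosomes: 212 of 276 had a summit on X (76.8%) and 239 of 336 on the autosomes (71.1%; Fisher's exact test, p = 0.118). The outer parts of the chromosomes had 13.4 peaks per bin and the central parts 14.5 (ratio 0.93, permutation test, two-sided, p = 0.174).

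**Figure D4:**
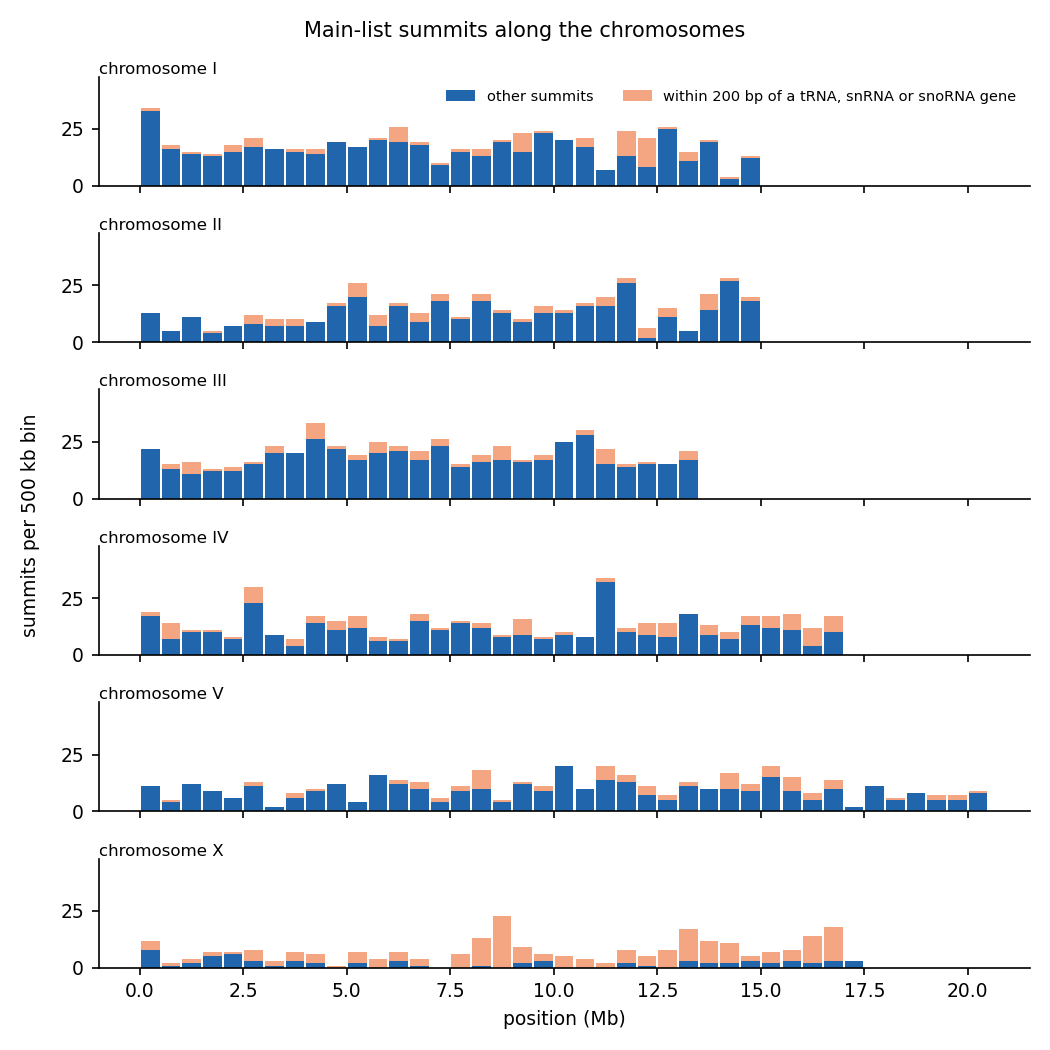
Main-list summits per 500 kb bin are plotted along each chromosome (Mb), split into those within 200 bp of a tRNA, snRNA or snoRNA gene (orange) and all others (blue). Only full bins are drawn, so some summits at chromosome ends are not shown. Of the 265 summits on X, 69 belong to the blue part.

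Sequence at the summits was richer in G and C than its flanks, and many words differed between them. Mean GC content was 45.3% in 100 bp at the summits and 35.99% in the flanks. On chromosomes I, III and V 1600 of 8192 words differed between summits and flanks past the threshold, and 1040 of them differed in the same direction on II, IV and X, 675 higher at summits and 365 lower. The word AAGGCGC was in 8.93% of summit windows and 0.893% of flanks on the first chromosomes (Fisher's exact test, adjusted p = 3.13e-38) and in 9.59% and 0.703% on the second. CGAGACC was in 9.50% of summit windows against 1.5% of flanks on the first chromosomes and 9.93% against 1.08% on the second. CGCGCGC was in 6.70% against 0.446% on the first and only 3.80% against 0.331% on the second, and TACCGTA in 7.72% against 1.02% and 6.62% against 1.16%. The word GGTTCGA, part of the internal B box that TFIIIC binds at tRNA genes, was in 6.25% against 0.829% on the first and 14.7% against 1.57% on the second. The second set includes X, where 193 of 265 peaks lay at tRNA genes, so the 2 sets differ in their kinds of site. The log2 odds ratio of GGTTCGA fell from 2.97 to 1.46 without summits at small RNA genes, where the word no longer passed in both sets of chromosomes. It was 4.47 among the stronger 1388 summits. For CGCGCGC it was 3.96, and 5.08 in replicate 2's list alone. The share of windows with GGTTCGA was 51.8% at tRNA genes (218 of 421 summits) and 1.16% at promoter summits away from small RNA genes. Among words lower at summits, CTGAAAA was in 5.23% of summit windows against 13.6% of flanks. Without summits at small RNA genes 565 words passed in both sets of chromosomes, 422 higher at summits and 143 lower. Neighbouring words overlap, so their number is not a number of motifs. The flanks were not matched to the summits in GC content, so passing in both sets does not separate a preferred sequence from that difference in composition.

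**Figure D5:**
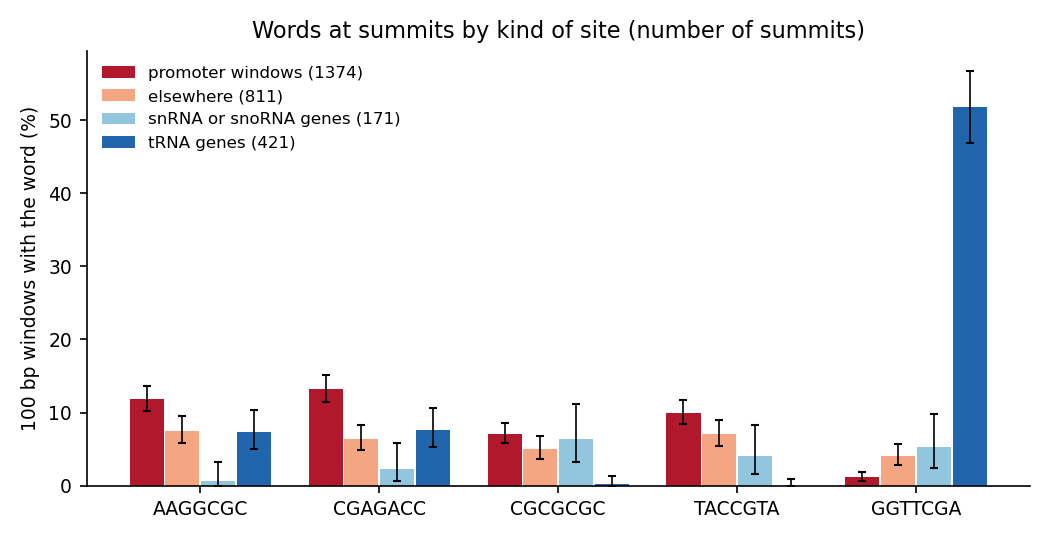
The percentage of 100 bp summit windows that hold each of 5 words is shown by kind of site, with exact 95% intervals. GGTTCGA is in 51.8% of windows at tRNA genes, while AAGGCGC is in 11.9% and TACCGTA in 9.97% of promoter windows away from small RNA genes.

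Stronger peaks were more often in promoters. Among the 695 strongest summits 62.9% were in promoter windows (437 of 695, interval 59.2 to 66.5%), among the next 694 52.3%, then 54.6%, and among the 694 weakest 47.1% (327 of 694, interval 43.4 to 50.9%). The strongest group exceeded the weakest by 15.8 percentage points (permutation test, two-sided, p = 2e-05, the smallest possible). The second group, with signals from 130 to 195, held the most tRNA summits, 26.7% against 13.7% in the strongest and 6.77% in the weakest. Without summits at small RNA genes, chosen after seeing the data, the difference was 26.2 points. It was 10.4 points in the other pooled list and 8.05 points in replicate 2's list alone (permutation p = 0.0174).

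The tagged gene itself had no strong peak. No peak past the threshold lay within 5 kb of D2030.7 in the main list, the other pooled list or the replicate 1 list. The replicate 2 list had 1, with its summit in an exon of the neighbouring gene D2030.12 and a signal of 45.4, rank 1673 of 1811, and it lay beyond 2 kb. Among the 67021 ranked candidates of the main comparison 14 peaks lay within 5 kb, the highest in an intron of prg-1, the Piwi Argonaute gene, with a signal of 75.2 and rank 2958.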

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

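The tests of transcript abundance, candidate peaks, small RNA genes, repeated sequence, a fixed set of regions and the presence of a B box were written down before their results were seen; the tests of muscle and intestine genes and of a missing B box as the whole cause or within tRNA product were chosen only after the result was seen. The readings of the candidate-peak test, of the transcript abundance test and of the test of repeated copies at tRNA genes were also altered after their values were seen. With 1 group and no second condition, no explanation by regulation was tested for any pattern.

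In the ranked true-replicate list 91 peaks were past the IDR threshold and absent from the thresholded list, and they were therefore in none of the comparisons made on thresholded lists, while values over whole ranked lists include them. They include the strongest peak of all, with a signal of 2629 (chromosome X, 15810931 to 15811190, no annotated gene), a cluster of 9 peaks on chromosome V between 7913397 and 7924708 with signals up to 1188, and 5 peaks at the array of 5S rRNA and spliced leader genes on chromosome V between 17119813 and 17129653, up to 352. Copies of the same sequence elsewhere are a candidate explanation: 87.9% of the 91 (interval 79.4 to 93.8%) had most of their 36-base words at 2 or more places of the assembly, against 8.07% of the 2777 kept peaks. A fixed set of regions removed from every list is another candidate, since 0 of 117 distinct left-out sites over the 4 lists (interval up to 3.10%) overlapped a kept peak of another list. Both hold together, and 224 kept peaks were as repeated, so repetition alone does not separate left-out from kept peaks.

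For the frequent binding at ribosomal protein genes, transcript abundance in the whole animal as the whole cause stays undecided. A summit was found at 0 of 37 vitellogenin and major sperm protein genes (upper bound 9.49%). It was found at 2 of 60 muscle and intestine genes (upper bound 11.5%). Both upper bounds are under the lower bound of 32.2% for ribosomal protein genes, so these genes were bound less often. Of the 37 genes 31 are major sperm protein genes. The comparison tests abundance only if the transcripts of these genes were abundant in these young adults. Transcript levels were not measured here, so no conclusion on abundance is drawn. Summits that belong to small RNA genes are not the cause, since without them the odds ratio was 11.2 (Fisher's exact test, adjusted p = 1.14e-19). Promoters that give peaks in any such experiment stay open: among genes with a candidate peak the odds ratio was 5.39 (Fisher's exact test, adjusted p = 6.63e-11). The rule written beforehand read a value above 1 as evidence against this explanation, and that reading was withdrawn after the value was seen, because the candidates come from the same experiment and cover 53.5% of protein-coding genes, unspecific promoters could also pass the threshold, and no list for another tagged protein or for the control was used here.

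Of the 612 tRNA genes 161 had no summit, and these lacked a match to the B box sequence GGTTCRANNCC in 45 cases and genes with a summit in 64 of 451, a difference of 13.8 percentage points (interval 6.12 to 21.4, Fisher's exact test, p = 0.000175). The match follows the product, with 71 of 109 genes that lack it in 4 products, so a missing match need not be a missing B box, although within product such genes also lacked a summit more often (pooled odds ratio 2.52, interval 1.26 to 5.06, permutation p = 0.0103). It is not the whole cause, since 72.0% of the genes without a summit had the sequence and 58.7% of the genes lacking it had a summit. Reads that could not be placed because of repeated copies were judged by the share of repeated 36-base words within 200 bp of each gene. The mean share was 15.7% without a summit and 13.3% with one, higher by 2.37 percentage points (bootstrap interval -0.33 to 5.19). The median was not higher (11.0 against 11.6%, permutation test, one-sided, p = 0.993). The rule written beforehand read such values as evidence against this cause for the genes as a set. That reading was withdrawn, because the windows are mostly flank and repeats inside a gene add little to the share. The margin that the rule allowed was also large beside these mean shares. The values therefore do not decide whether reads inside the genes could be placed, nor do they exclude this cause for a subset of highly repeated genes. Of the 161 genes 85 had a ranked candidate below the threshold within 200 bp, so part of the absence may lie in the threshold.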

How the results depend on the processing

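Of 432 values computed under alternatives, 377 kept their direction and their side of the threshold, or stayed within a fixed fold (counts) or an interval (correlations) of the main value. The alternatives without summits at small RNA genes, the background of summits below the threshold for non-coding genes, and the share of genes bound on X were chosen after seeing the data. The share of summits in promoters (2.48 to 3.87-fold over background), the lower share in exons and introns, the excess at tRNA genes (31.4 to 92.6-fold), the lower number of peaks on X (ratio 0.16 to 0.68), the higher promoter share of strong peaks (8.05 to 26.2 points) and the overlap of replicates (50.4 to 63.1% of replicate 1, 68.2 to 85.97% of replicate 2) passed under each alternative run. Intergenic summits were the exception: 0.99-fold with the 500 bp promoter window (permutation p = 0.749) and 1.11-fold against summits below the threshold, where the direction turned; the cause was not tested. The stronger peaks of each list, above the median signal, number 1232, 905, 1388 and 1541 peaks in replicate 1, replicate 2, the main and the other pooled list by construction. Over all ranked peaks the correlation of the inputs was 0.29 (Spearman) and 0.47 (Pearson). The number of words found in both sets of chromosomes was 671 without replicate 1 and 890 without replicate 2, 663 among the stronger 1388 summits, 682 with 60 bp windows and 565 without summits at small RNA genes; the cause was not tested. Lists bound less often numbered 3 among the stronger summits against 7. With 1 replicate's list alone the promoter share was 2.52 to 2.66-fold, the tRNA excess 66.9 to 78.5-fold, the X ratio 0.50 to 0.64, the difference by signal 8.05 to 15.7 points, lists bound more often 9 to 12 and lists bound less often 5. Within 2 kb of the tagged gene 0 thresholded peaks remained over the 4 lists. Of 252 gene list values 217 were unaltered in call and direction, 28 lost the threshold, 1 gained it (chaperones, when each summit counted for every gene whose window holds it) and 6 turned without passing. The turned ones were muscle genes (log2 odds ratio 0.13 with the 500 bp window and 0.13 stratified by upstream length) and stress genes (0.12 in the other pooled list, 0.10 and 0.38 with 1 replicate left out, 0.35 among the stronger summits). The rRNA class ranged from 3.24-fold without replicate 1 to 0-fold without replicate 2, and antisense RNA genes to 1.17 and 1.19-fold without replicate 1 and 2 and 1.11-fold within 500 bp, none past the threshold. Among genes with a ranked peak in the promoter, 9 of the 13 lists bound more often and 5 of the 7 bound less often kept their call. Of the 25 named strongest genes 21 kept a summit with the 500 bp window. Leaving out a replicate gives no value for the overlap, the correlation or the counts, which need both. No paired analysis was possible because there is 1 group. Depth is unknown, so it cannot be said how the difference in peak number between the replicates relates to it.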

Other observations

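The words in the first paragraph were chosen only after the data were seen, and nothing here was tested. Shares of some words differed between the strongest and the weakest summits. Away from small RNA genes, TACCGTA was in 15.97% of windows at the strongest summits (interval 12.9 to 19.5%, 80 of 501) and 4.57% at the weakest (3.08 to 6.5%, 29 of 634), CGAGACC in 15.2% and 5.36%, AAGGCGC in 12.6% and 4.42%, and CGCGCGC in 11.0% and 3.94%. At tRNA genes TACCGTA was in 0 of 421 windows (interval up to 0.872%) and CGCGCGC in 1, while AAGGCGC was in 7.36% and CGAGACC in 7.60%.

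The tRNA genes of each amino acid were bound. The share with a summit ran from 55.0% for tRNA-Met (11 of 20, interval 31.5 to 76.9%) and 55.6% for tRNA-Gln (15 of 27) to 87.2% for tRNA-Leu (34 of 39) and 92.3% for tRNA-Cys (12 of 13, interval 64 to 99.8%). The single annotated tRNA-Sec gene had a summit with a signal of 263. The median signal of bound tRNA genes was 166 on X and 145 on the autosomes. Summits at snoRNA genes had a median signal of 218 and those at snRNA genes 215, against 151 at tRNA genes and 131 at promoters away from these.

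The share of peaks on chromosome X differed between the replicates, at 9.54% of replicate 1 peaks and 12% of replicate 2 peaks past the threshold, and 8.85% and 14.2% of their ranked candidates. Of the main-list peaks 52.9% overlapped thresholded peaks of both replicates and 19.8% of neither. Each replicate's list has its own threshold, and every main-list peak has a signal from both inputs in its ranked form. The 19.8% is therefore not a share without signal in either replicate. Among the 10 peaks with the highest signal past the IDR threshold in the ranked true-replicate list, 2 were left out of the thresholded list.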
